A study of Homo sapiens and Mus musculus with 41 samples.

How the data were processed

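RNA sequencing read counts were analysed for 41 libraries from 2 macrophage cell lines, 20 from the mouse line J774 and 21 from the human line U937. Groups were taken from the sample labels: control, activated, and activated with the extract OBE100 (called OBE here), the mixture M1 (UA, OA and UAL together), or UA, OA or UAL alone. Each of the 7 groups of a line held 3 libraries, except J774 treated with OA, which held 2. The replicate number in each label named the library within its group. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. UA, OA and UAL are used here as the labels give them. The labels used do not say whether the U937 control cells received phorbol ester, and they name no vehicle control.

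The values are raw read counts per gene, deposited as one table per cell line. Per the file headers, the authors counted reads over exons joined by gene with featureCounts 2.0.2, using GENCODE 39 for human and GENCODE M28 for mouse. Per the file headers, the command set no strand option, no read-pair option and no option for reads with several alignments, and its input alignments were called filtered, by a filter not given in the sources used here. Per the submitters' processing notes, FastQC, Trimmomatic, STAR, DESeq2 and the builds hg19, GRCh38 and GRCm39 were used, with roles and versions not given in the sources used here. Near-identical genes, such as the metallothioneins and HSPA1A and HSPA1B, can lose or share reads under such counting. The same holds for overlapping genes and for antisense pairs, since reads from both strands were counted together. Values for these genes are therefore uncertain.

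Total counts ran from 13867583 to 15182082 per library in J774 and from 16033675 to 16604487 in U937. TMM factors ran from 0.774 to 1.103 in J774 and from 0.903 to 1.117 in U937. Mitochondrial genes held 2.32 to 4.71% of counts in J774 and 2.24 to 5.65% in U937. No count column lay outside the samples (0 in either table). To look for libraries deposited more than once, chi-square statistics per degree of freedom were computed for 190 pairs of J774 libraries and 210 pairs of U937 libraries over genes with at least 20 counts in the pair. The lowest values were 2.48 and 3.39, and the lowest within a group were 51.85 and 38.52, above the value of sampling noise alone, so each library was counted once.

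U937 identifiers were matched to symbols through a supplied table of gene names, which named 61415 of 61587 genes. For 40177 of them a RefSeq gene of assembly GRCh38.p14 had the same symbol and chromosome, and 99.9% of these overlapped in position. No mouse symbols were supplied, and 0 J774 identifiers could be named. Gene lists, named genes and the comparison of the same genes in both lines were therefore not run for J774, and at most 2 risen and 2 fallen identifiers are given. Coordinates are those of the count tables, on GRCh38 with GENCODE 39 and on GRCm39 with GENCODE M28.

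Differential expression was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), by its quasi-likelihood F test with TMM normalization and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Genes were kept by edgeR's filter on the groups, which left 13383 of 55414 genes in J774 and 14329 of 61587 in U937. All libraries of a line entered one fit, because each group was small. There were 12 comparisons per line: activation, the 5 treatments against activated libraries, 5 direct comparisons (OBE with M1, M1 with UA, and the pairs of UA, OA and UAL), and the difference between the M1 effect and the sum of the UA, OA and UAL effects. The groups, the fit without a block, the gene lists, the rule for named genes and the other settings first listed at the end were fixed before the data were examined. Fold changes are log2 values with standard errors, and CPM are means ± SD over the 3 libraries of a group.

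The replicate numbers were then checked for pairing. Deviations of log2 CPM (prior count 2) from the group means were correlated across genes with a mean CPM over 8, which were 8942 genes in J774 and 8681 in U937. Libraries with the same number had correlations of at least 0.19 in J774 (57 pairs, median 0.81) and at least 0.30 in U937 (63 pairs, median 0.79). Libraries with different numbers had medians of -0.52 and -0.32, and reached 0.71 in J774, above the lowest value of a shared number there, and 0.11 in U937. Taking deviations from the means of such small groups makes these medians negative where libraries with the same number correlate. The negative medians are therefore no separate evidence of pairing. The best match of each library bore its own number in 20 of 20 and 21 of 21 cases. The numbers thus paired the libraries, by the data and by the labels' numbering, and the fit with the replicate number as a block, one of the settings fixed beforehand, is given beside the fit without it. Printing blocked values first where the call rests on them, and applying the rule for named genes to the blocked fit, were chosen after the data had been seen. There, no overlap between groups was replaced by the same direction in each of the 3 pairs.

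The rule named the 8 largest rises and 8 largest falls in activation, OBE and M1, and the 4 largest of each in the other comparisons, among genes past the threshold with a mean of at least 5 CPM in the higher group, a proper symbol and no overlap between the groups. It added up to 4 members of each list with the smallest p, and IL1B, IL6, TNF, CXCL10, CCL2, NOS2, PTGS2, IL10 and HMOX1. A total of 30 gene lists was fixed, of which 29 had at least 2 members tested in U937. The list of epithelial markers had 0 of 7 members tested. Lists were tested with camera on log2 CPM, two-sided, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted by Benjamini-Hochberg over the lists of a comparison. Counts of list members are also given adjusted over the list alone.

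Overlaps between comparisons that share the activated libraries were set beside 100 simulated data sets with no effect. The activated libraries could not be split, since 1 of the parts would have held fewer than 2 of them. The tests were tried on simulated counts with 100 genes changed 1.5-fold and 100 changed 3-fold in OBE against activated libraries. Without a block, edgeR recovered 0 and 62 of them in J774 (13210 genes) and 27 and 96 in U937 (14160 genes). With the block, it recovered 16 and 96 in J774, with 3 false calls, and 77 and 100 in U937, with 4 false calls. DESeq2 with the block recovered 45 and 98 in J774, with 21 false calls, and 81 and 100 in U937, with 9. Genes were simulated independently, with the dispersions of the blocked fit and the same change in each replicate number. False calls in real data whose replicates disagree are therefore not measured. Other settings fixed beforehand were DESeq2 1.42.0, RLE size factors in place of TMM, no filter on low counts, only the libraries of a comparison, the replicate block, an estimated correlation for the lists, and leaving out each library in turn. Added after the data had been seen were DESeq2, RLE, no filter, a correction for exon length (a lowess trend of span 0.4 in each library) and leaving out all libraries of 1 replicate number, each with the block.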

Results

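Transcript levels were measured by RNA sequencing in J774 cells, a mouse macrophage line, and U937 cells, a human monocytic line that becomes macrophage-like after phorbol ester. Per the labels, activated and treated U937 cells were differentiated with 100 nM phorbol myristate acetate for 72 h. The labels used here do not say whether U937 control cells received it, so the comparison called activation in U937 may hold differentiation as well. Activation lasted 24 h with lipopolysaccharide, a bacterial activator of Toll-like receptors, and 20 ng/ml interferon gamma. Treated cells were given 100 µg/ml OBE, 78 µg/ml M1, 47.7 µg/ml UA, 14 µg/ml OA or 16.3 µg/ml UAL for 6 h. The doses of UA, OA and UAL sum to 78 µg/ml, the dose of M1. No vehicle control is named in the labels used, so differences from activated libraries include any effect of a solvent. Each group of each line had 3 libraries, except 2 for OA in J774, and library totals were 13867583 to 15182082 counts in J774 and 16033675 to 16604487 in U937. The design asks whether activation took place, and what the extract, the mixture and each compound changed in activated cells.

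Most activated and treated libraries with the same replicate number lay close together in both lines. In J774, control replicate 1 (-40.2 and -50.7 on the first and second principal components) lay nearer to control replicate 3 (-76.8 and -14.8) than to the other libraries of its number, and M1 replicate 1 (83.2 and -83.7) also stood apart. In J774, the activated and treated libraries of replicate 3 scored -57.7 to -63.8 on the first principal component, while those of replicate 1 scored 52.8 to 83.2. In U937 the activated and treated libraries of replicate 1 scored 35.6 to 43.6, those of replicate 2 -0.9 to 3.9 and those of replicate 3 -27.7 to -32.9. Values from the fit with the replicate number as a block are therefore given beside those without it.

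**Figure D1:**
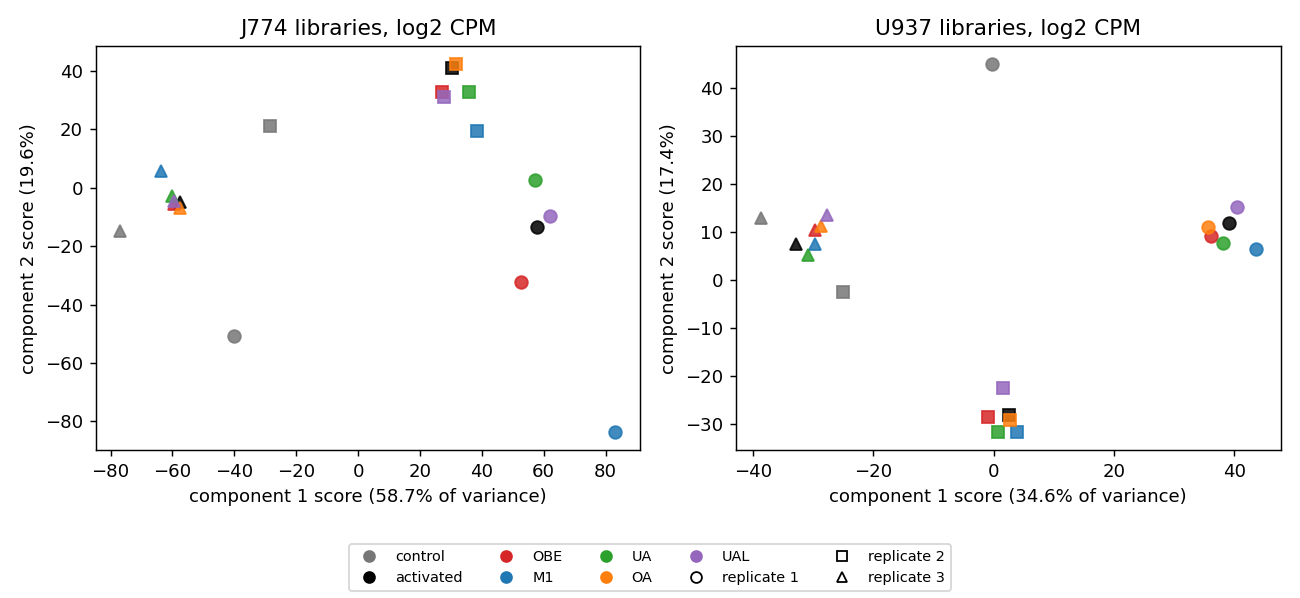
Scores of each library on the first and second principal components of log2 CPM, in J774 (58.7 and 19.6% of variance) and U937 (34.6 and 17.4%), coloured by group and shaped by replicate number. Most activated and treated libraries lie together by replicate number, except M1 replicate 1 in J774, and the control library of replicate 3 lies closer to those of its own number than the control libraries of replicates 1 and 2 do.

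In U937, IL6, CXCL8 and IL1B were higher and FABP5 and ACACA were lower in activated than in control libraries, a comparison that may include the effect of phorbol ester. The cytokine IL6 (ENSG00000136244.12, chromosome 7, 22725884 to 22732002) was at 29.9 ± 24 CPM in activated and 1.5 ± 2.15 CPM in control libraries (SD, n = 3 each), a log2 fold change of 4.30 (SE 1.01). The neutrophil chemokine CXCL8 was at 11400 ± 5250 against 1620 ± 764 CPM, a log2 fold change of 2.81 (SE 0.50). The inflammatory cytokine IL1B was at 16600 ± 7190 against 2780 ± 866 CPM, a log2 fold change of 2.58 (SE 0.54). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.0476 for IL6, 0.0135 for CXCL8 and 0.0321 for IL1B. In total 144 genes changed, 77 up and 67 down, and with the replicate number as a block 2509 changed, 1232 up and 1277 down. At an unadjusted p under 0.05 there were 1893 and 4373 genes, and DESeq2 called 452 and 2461. Without the filter on low counts, 794 were called without the block.

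The other large rises in U937 were the chemokines CXCL2 (log2 fold change 3.70), CCL13 (3.19), CCL20 (2.83), CXCL5 (2.64) and CCL1 (2.61), and CLEC4E (2.86), a pattern receptor for mycobacterial glycolipid. The largest falls were ZBED3 (-1.78), TOGARAM2 (-1.31), the fatty acid binding protein gene FABP5 (-1.26), PAQR5 (-1.21), FCMR (-1.17), TMCC2 (-1.16), the peroxisomal oxidase gene ACOX2 (-1.08) and DOP1B (-1.07). Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 2.25e-05 for DOP1B to 0.0441 for TMCC2. With the block, the growth factor genes CSF3 (4.45, adjusted p 2.28e-05) and CSF2 (3.39, adjusted p 2.04e-05) rose, as did SERPINA9 (4.47), IL36G (3.12) and HCAR3 (3.04). The block also gave falls of FABP4 (-2.22) and of the scavenger receptor gene CD36 (-1.59, adjusted p 3.16e-05), and of ADCY1 (-1.98), ANGPT4 (-1.81), DUSP2 (-1.69), GPD1 (-1.67) and CD244 (-1.58). Key genes below the threshold without the block and past it with the block, in the same edgeR test, were TNF (1.83, adjusted p 0.00084), PTGS2, which makes prostaglandin precursors (2.86, adjusted p 0.0021), CCL2 (0.89, adjusted p 1.86e-05), IL10 (0.89, adjusted p 0.000228) and CXCL10 (1.30, adjusted p 0.032). Without the block the edgeR adjusted p of these genes was 0.197, 0.113, 0.0611, 0.434 and 0.752. CXCL10 did not pass in DESeq2 with the block, and without the block and without activated replicate 3 its log2 fold change was -0.29. HMOX1 had a log2 fold change of -0.41 (adjusted p 0.118 with the block) and NOS2 was below the filter.

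Of 24 inflammatory cytokine and chemokine genes in U937, 6 rose and 0 fell over all genes tested, 18 rose and 1 fell adjusted over the list alone, and 21 rose and 1 fell with the block. The camera adjusted p was 3.47e-14, and adjusted p = 0.0988 with an estimated correlation. Of 19 NF-kB targets and feedback regulators, 2 rose and 0 fell, ZC3H12A (1.58) and TNFAIP3 (0.81), both brakes on inflammatory signalling, with 12 and 0 adjusted over the list alone and 16 and 0 with the block. Their camera adjusted p was 1.93e-12, and adjusted p = 0.192 with an estimated correlation. Among 26 Toll-like receptor signalling genes 2 rose, the lipopolysaccharide co-receptor CD14 (1.64) and TLR2 (0.86), with 3 adjusted over the list alone and 6 up and 2 down with the block. The list's camera adjusted p was 0.0445, and adjusted p = 0.265 with an estimated correlation, and the block ended the call, at a camera adjusted p of 0.0785. Among 25 macrophage markers 3 rose, CD14, MMP12 (1.92) and FCGR2A (1.05), 6 rose and 3 fell adjusted over the list alone, 7 rose and 6 fell with the block, and camera gave an adjusted p of 0.135. In the inflammasome list 2 of 16 rose, IL1B and CASP4 (0.37), with 4 up and 1 down adjusted over the list alone, 6 up and 2 down with the block, a camera adjusted p of 0.0124, and adjusted p = 0.169 with an estimated correlation. The single member of 19 antigen presentation genes that rose without the block was HLA-E (0.71), also 1 adjusted over the list alone, against 4 with the block, and camera gave an adjusted p of 0.607.

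Among the metabolic lists in U937, of 17 LXR targets and fatty acid synthesis genes 2 fell, ACACA (-0.52), the first step of fatty acid synthesis, and LPCAT3 (-0.63), with 3 adjusted over the list alone and 7 with the block. The camera adjusted p was 0.00576, and adjusted p = 0.433 with an estimated correlation. Of 12 PPAR targets and lipid storage genes 1 fell, FABP5, also 1 adjusted over the list alone, against 2 up and 5 down with the block, at a camera adjusted p of 0.0485, and adjusted p = 0.192 with an estimated correlation. Of 14 alternative activation genes 1 fell, PPARG (-0.74), also 1 adjusted over the list alone, against 3 up and 3 down with the block, at a camera adjusted p of 0.703. Of 24 glycolysis and hypoxia genes none passed alone (0) and 2 rose adjusted over the list alone, while 12 rose and 1 fell with the block, among them PFKFB3 (1.00), a driver of glycolysis. Its camera adjusted p was 0.000858, and adjusted p = 0.433 with an estimated correlation. Of 32 cell cycle genes 0 passed either way without the block and 11 fell with it, among them the mitotic kinase gene PLK1 (-1.06), at a camera adjusted p of 6.71e-05, and adjusted p = 0.215 with an estimated correlation. Of 7 metallothionein and zinc export genes 1 rose adjusted over the list alone and 5 rose with the block, among them MT2A (1.40), which binds metal ions. The camera adjusted p was 0.014, and adjusted p = 0.434 with an estimated correlation.

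In the p53 target and apoptosis list 2 of 19 rose, PMAIP1 (0.89), a promoter of cell death, and BTG2 (1.02), with 3 adjusted over the list alone and 8 up and 1 down with the block. The camera adjusted p was 0.00331, and adjusted p = 0.291 with an estimated correlation. Of 8 aryl hydrocarbon receptor targets SERPINB2 (1.25) rose, 1 also adjusted over the list alone and 3 with the block, at a camera adjusted p of 0.0342, and adjusted p = 0.211 with an estimated correlation. Immediate early genes (22) and genes of endoplasmic reticulum stress and the integrated stress response (29) had 0 members past the threshold without the block, also adjusted over the list alone. With the block 8 and 10 of them rose and 1 of each fell. Their camera adjusted p without the block were 0.0238 and 0.0242, and adjusted p = 0.433 for each with an estimated correlation. The interferon response list had 0 of 35 past the threshold and 2 adjusted over the list alone, at a camera adjusted p of 0.127. With the block 7 of its members rose, among them SOCS3 (2.01), a feedback inhibitor of cytokine signalling, at a camera adjusted p of 0.00581, and adjusted p = 0.566 with an estimated correlation. The cholesterol synthesis list fell with the block at a camera adjusted p of 0.014 and adjusted p = 0.336 with an estimated correlation, with 1 of 24 up and 5 down. The myeloid progenitor and granule list had a blocked camera adjusted p of 0.0455 and adjusted p = 0.259 with an estimated correlation, with 2 of 15 up and 5 down. For lists that camera called in neither fit, the camera adjusted p without the block was 0.313 for NRF2 targets, 0.112 for heat shock, 0.924 for oxidative phosphorylation, 0.469 for lysosome and autophagy, 0.308 for ABC transporters and drug metabolism, 0.0702 for ribosomal proteins and 0.308 for mitochondrially encoded genes. These lists had 0 members past the threshold without the block. With it, 7 of 20 NRF2 targets rose and 2 fell, 3 of 28 lysosome and autophagy genes rose and 4 fell, and 1 rose and 0 fell in each of the others except the mitochondrially encoded genes (0). Among lists of other cell types, the endothelial genes VWF (-1.01) and PECAM1 (-0.48) were lower in activated cells, 1 of 2 past the threshold, 2 adjusted over the list alone and 2 with the block. Their camera adjusted p was 0.000656, and adjusted p = 0.0988 with an estimated correlation, while fibroblast markers (3 tested) had a camera adjusted p of 0.924 and lymphocyte markers (5 tested) one of 0.598, with 0 and 2 members up with the block. Activation calls without a block fell to 10 without control replicate 1, 15 without activated replicate 1, 23 without control replicate 2 and 22 without activated replicate 2, and were 255 without activated replicate 3 and 0 when only these 6 libraries were fitted.

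**Figure D2:**
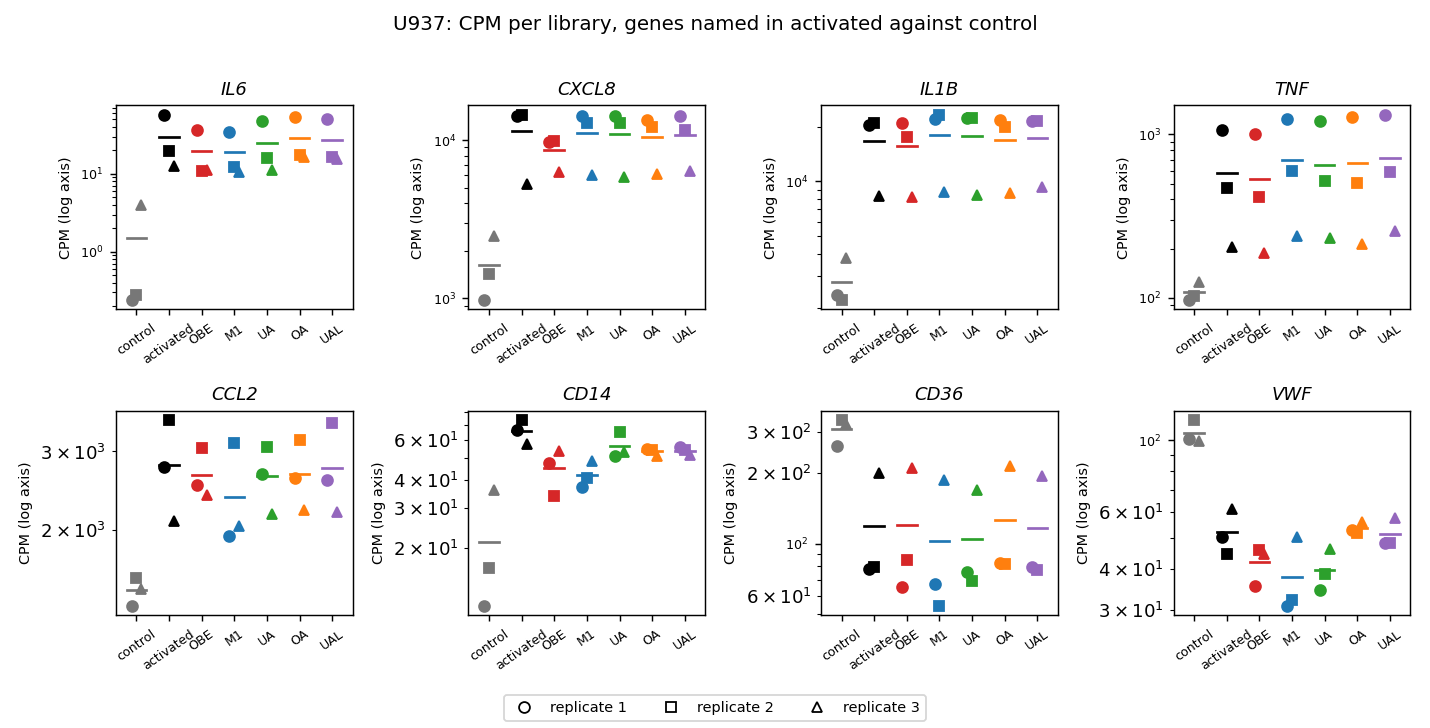
CPM on log axes of 8 genes in each U937 library by group, with the group mean as a line and the replicate number as the point shape (3 libraries per group). IL6 lies at a mean of 29.9 CPM in activated and 1.5 CPM in control libraries, and replicate 3 shows the smallest difference between them.

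In J774, the comparison of activated with control libraries gave 0 genes past the threshold in edgeR's quasi-likelihood test without the block, against 552 at an unadjusted p under 0.05, and DESeq2 called 8. With the block 1366 genes changed, 629 up and 737 down, and DESeq2 with the block called 1715. Without the block and without the filter, edgeR called 185. The mitochondrial share of counts was 3.24 ± 0.88% in activated and 4.2 ± 0.71% in control libraries (SD, n = 3 each), lower by 1.54, 0.86 and 0.49 percentage points in replicates 1, 2 and 3. The largest rises with the block were ENSMUSG00000029379.11 (chromosome 5, 90933962 to 90937459), at 88.4 ± 91.1 against 0.863 ± 1.26 CPM (n = 3 each) and a log2 fold change of 6.57 (SE 0.63), and ENSMUSG00000029409.8 (chromosome 5, 92357752 to 92363267), at 6.23 (SE 0.76). The largest fall was ENSMUSG00000022033.10 (chromosome 14, 66043286 to 66055271), at -4.78 (SE 1.11) with the block and -1.45 without it. Their edgeR adjusted p with Benjamini-Hochberg adjustment were 1.24e-05, 0.000109 and 0.0123 with the block, and 0.99 for each without it. The blocked count was 539 without the libraries of replicate 1, 106 without replicate 2 and 1305 without replicate 3.

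In U937, OBE raised MT1X, HMOX1 and the chaperone gene HSPA8 and lowered IRF8 and NR4A3, in the fit with the replicate number as a block. The metallothionein gene MT1X (ENSG00000187193.9, chromosome 16, 56682470 to 56684196) was at 65.3 ± 46.9 CPM with OBE and 23.6 ± 9.53 CPM in activated libraries (SD, n = 3 each), a log2 fold change of 1.34 (SE 0.21), in a gene family whose near-identical members can share reads. HMOX1 (chromosome 22, 35380361 to 35394214), which degrades haem, was at 136 ± 89.2 against 71.5 ± 27.5 CPM, a log2 fold change of 0.88 (SE 0.18). In replicates 1, 2 and 3 it was at 236, 65.5 and 107 CPM with OBE, against 82.9, 40.1 and 91.4 CPM in activated libraries. In replicate 3, HMOX1 was at 113 CPM with OA and 103 CPM with UA. IRF8 (chromosome 16, 85899162 to 85922606), a transcription factor of the myeloid lineage, was at 19.4 ± 6.95 against 38.3 ± 16.7 CPM, a log2 fold change of -0.95 (SE 0.15). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, their blocked adjusted p were 0.00498, 0.0128 and 0.00498, against 0.629, 0.784 and 0.759 without the block. With the block 406 genes changed, 118 up and 288 down. Without it, edgeR called 0 genes, with 987 at an unadjusted p under 0.05, and DESeq2 called 31. With the block DESeq2 called 652, and edgeR without the filter 849.

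Beside MT1X, the largest rises with OBE in U937 were MT1G (1.24), MT1E (1.09), the nuclear RNA MALAT1 (0.88), HMOX1, SLFN11 (0.79), NLE1 (0.77) and C15orf61 (0.74). The largest falls were RASL12 (-1.62), the orphan nuclear receptor gene NR4A3 (-1.53), KIR3DX1 (-1.41), CSPG4 (-1.20), the cytokine gene OSM (-1.19), EPHA10 (-1.17), UCN2 (-1.07) and CUX2 (-1.06). Of the key cytokine genes none passed the test. The blocked log2 fold change was -0.58 for IL6 (edgeR Benjamini-Hochberg adjusted p 0.391), -0.61 for PTGS2, -0.55 for CXCL10, -0.15 for IL10, -0.13 for TNF, -0.08 for IL1B and -0.05 for CCL2. The inflammatory cytokine and chemokine list had 0 of 24 members past the threshold, also adjusted over the list alone, at a blocked camera adjusted p of 0.179.

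Members of several stress lists rose with OBE in U937. Of 17 heat shock genes 4 rose with the block and 7 adjusted over the list alone, among them AHSA1 (0.35), HSPA8 (0.33) and HSPA1B (0.64), which encode a co-chaperone and chaperones of the Hsp70 family. The blocked camera adjusted p was 2.67e-05, and adjusted p = 0.139 with an estimated correlation. In replicate 3, HSPA1B was at 80.7 CPM with OBE, 75.9 CPM in the activated library and 83 CPM with each of UA, OA and UAL. Of 7 metallothionein and zinc export genes 3 rose and 6 adjusted over the list alone, at a blocked camera adjusted p of 0.00106, and adjusted p = 0.383 with an estimated correlation. Of 29 genes of endoplasmic reticulum stress and the integrated stress response 5 rose and 10 adjusted over the list alone, among them SDF2L1 (0.68), the chaperone gene HSPA5 (0.33) and the stress transcription factor gene DDIT3 (0.64). Their blocked camera adjusted p was 0.0354, and adjusted p = 0.644 with an estimated correlation. Of 20 NRF2 antioxidant genes HMOX1 and OSGIN1 (0.52) rose and ABCC1 (-0.35) fell, 3 and 1 adjusted over the list alone, at a blocked camera adjusted p of 0.0354, and adjusted p = 0.358 with an estimated correlation. Of 24 cholesterol synthesis and uptake genes MVK (0.59) and SC5D (0.34) rose, 4 up and 1 down adjusted over the list alone, at a blocked camera adjusted p of 0.00802, and adjusted p = 0.449 with an estimated correlation. Ribosomal proteins had 0 of 25 past the threshold, also adjusted over the list alone, with a median log2 fold change of 0.14, a blocked camera adjusted p of 0.00167, and adjusted p = 0.644 with an estimated correlation. Across 8681 genes, the OBE differences had Spearman correlations with exon length of -0.25, -0.15 and -0.15 in replicates 1, 2 and 3.

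Of 22 immediate early genes 7 fell and 1 rose with OBE, 8 and 3 adjusted over the list alone, among them the transcription factor genes NR4A3, EGR2 (-0.59), FOS (-0.42) and JUNB (-0.35), while MYC (0.38) rose. Their blocked camera adjusted p was 0.00802, and adjusted p = 0.37 with an estimated correlation. Of 35 interferon response genes IRF8 alone fell, also 1 adjusted over the list alone, at a blocked camera adjusted p of 0.00189, and adjusted p = 0.644 with an estimated correlation. Of 8 aryl hydrocarbon receptor targets 2 fell and 3 adjusted over the list alone, TIPARP (-0.49) among them, at a blocked camera adjusted p of 0.012, and adjusted p = 0.37 with an estimated correlation. The alternative activation list had 0 of 14 past the threshold over all genes, and 1 up and 7 down adjusted over the list alone, with CLEC10A at -0.50 and CD163 at -0.46. The macrophage marker list had 0 of 25 over all genes and 5 down adjusted over the list alone, with CSF1R at -0.40 and CD14 at -0.56. These lists held with the block under both correlations, at camera adjusted p of 0.00167 and 0.00189 with the preset, and adjusted p = 0.0297 for each with an estimated correlation. Without the block their camera adjusted p were 0.0671 and 0.0279, and adjusted p = 0.256 and 0.191 with an estimated correlation.

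Among other lists in OBE, single members that passed with the block were VEGFA (-0.51), a growth factor of blood vessels, TAB2 (-0.36) of Toll-like receptor signalling, the cholesterol exporter gene ABCA1 (-0.77), the lipid droplet gene PLIN2 (0.51), SPN (-0.40), and PCNA (0.47) and RRM2 (-0.64) of the cell cycle list. For glycolysis and hypoxia (24 genes) 1 fell, 2 adjusted over the list alone, at a blocked camera adjusted p of 0.0354, and adjusted p = 0.553 with an estimated correlation. For Toll-like receptor signalling (26 genes) 1 fell, 2 adjusted over the list alone, at a blocked camera adjusted p of 0.0271, and adjusted p = 0.37 with an estimated correlation. For NF-kB targets 0 of 19 passed, also adjusted over the list alone, at a blocked camera adjusted p of 0.0396, and adjusted p = 0.752 with an estimated correlation. The mitochondrial share of counts differed between OBE and activated libraries by 0.58, 2.04 and -1.83 percentage points in replicates 1, 2 and 3. The 406 calls became 0 without the libraries of replicate 1, 0 without replicate 2 and 1817 without replicate 3. Of the 406, 380 were among those 1817, and all 406 kept their direction when any replicate number was left out. The 406 were selected on all 3 replicate numbers, so both are largely given by that selection and are no separate support.

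**Figure D3:**
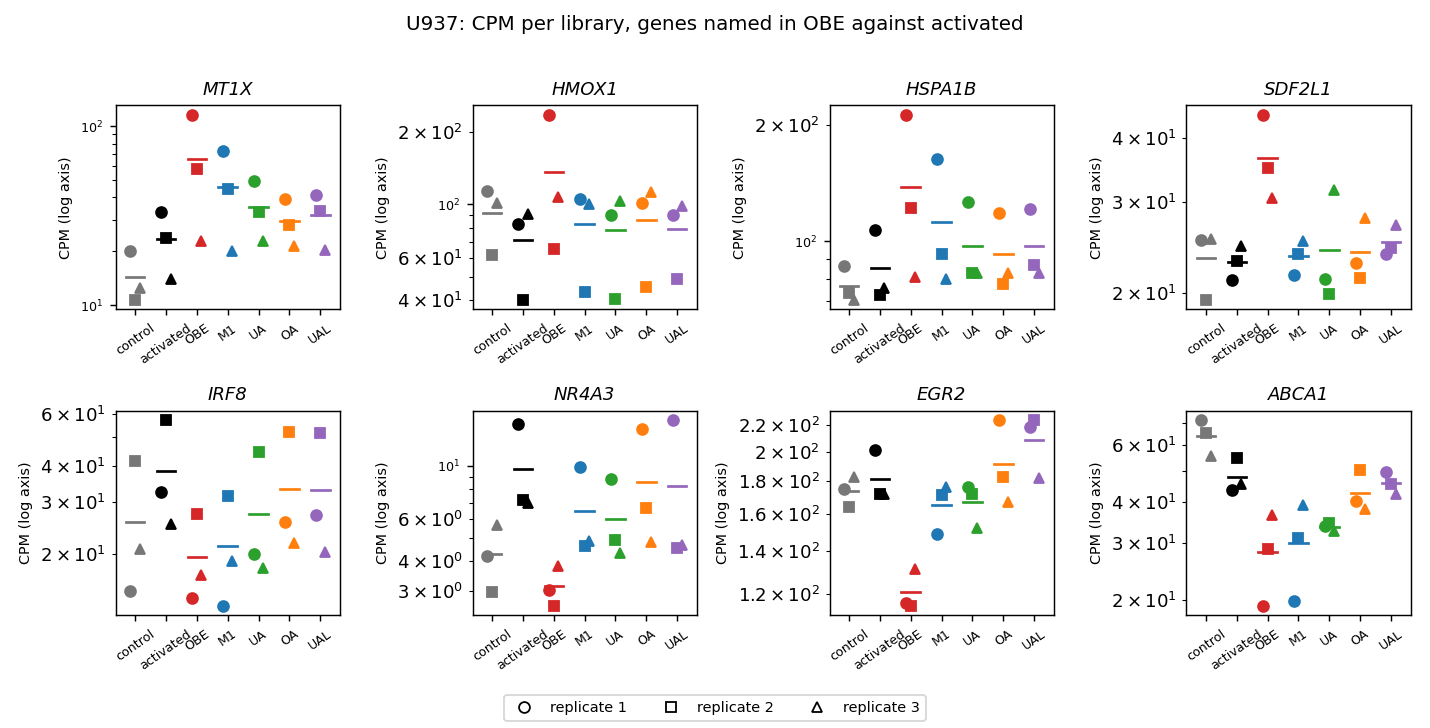
CPM on log axes of 8 genes in each U937 library by group, with the group mean as a line and the replicate number as the point shape (3 libraries per group). MT1X lies at a mean of 65.3 CPM with OBE and 23.6 CPM in activated libraries, with the means for M1, UA, OA and UAL between them.

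In U937, M1 raised the zinc exporter gene SLC30A1 and lowered IRF8, in the fit with the block. SLC30A1 (chromosome 1, 211571568 to 211579161) was at 136 ± 58 against 71.3 ± 11.3 CPM in activated libraries (SD, n = 3 each), a log2 fold change of 0.87 (SE 0.17). IRF8 was at 21.2 ± 9.26 against 38.3 ± 16.7 CPM, a log2 fold change of -0.84 (SE 0.15). The other falls named by the rule were RASL12 (-1.28), RASGRF1 (-0.97), TMPO (-0.80), the gap junction gene GJB2 (-0.73), COL22A1 (-0.72), CORO2B (-0.61) and MYH14 (-0.52). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the blocked adjusted p were 0.0421 for SLC30A1 and 0.0272 for IRF8, and each was 1 without the block. With the block 1 gene rose and 13 fell. Without it edgeR called 0 genes, with 419 at an unadjusted p under 0.05, and DESeq2 also called 0. With the block DESeq2 called 102, and edgeR without the filter 274. The blocked calls became 0 without replicate 1, 0 without replicate 2 and 499 without replicate 3.

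Of 7 metallothionein and zinc export genes with M1, SLC30A1 rose and 6 rose adjusted over the list alone, with MT1X at 0.89 and MT1G at 0.83. The blocked camera adjusted p was 0.000109, and adjusted p = 0.37 with an estimated correlation. Alternative activation genes had 0 of 14 past the threshold, and 1 up and 7 down adjusted over the list alone, at a blocked camera adjusted p of 0.000767, and adjusted p = 0.0219 with an estimated correlation. Macrophage markers had 0 of 25, also adjusted over the list alone, at a blocked camera adjusted p of 0.00236, and adjusted p = 0.0219 with an estimated correlation. Without the block the estimated correlation gave 0.204 and 0.0868 as adjusted p for these lists. The endothelial genes VWF (-0.47) and PECAM1 (-0.27) gave 0 of 2 over all genes and 2 adjusted over the list alone, at a blocked camera adjusted p of 0.0228, and adjusted p = 0.312 with an estimated correlation. The key cytokine genes did not pass, with IL6 at -0.60, CXCL10 at -0.54, CCL2 at -0.24, IL10 at -0.05, PTGS2 at 0.05, IL1B at 0.11 and TNF at 0.27, and HMOX1 was at 0.19.

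For UA, OA and UAL alone in U937 no gene passed the threshold in edgeR with or without the block (0 each), and DESeq2 also called 0. Without the filter on low counts and with the block, edgeR called 30, 1 and 9. At an unadjusted p under 0.05 there were 167, 94 and 126 genes without the block and 737, 336 and 429 with it. All but the 737 lay below a share of 0.05 of the 14329 genes tested, the share expected with no effect. The test was thus conservative, and 0 calls do not show that nothing changed. The doses differed (47.7, 14 and 16.3 µg/ml), so the values stand side by side. MT1X had blocked log2 fold changes of 0.59, 0.37 and 0.46 with UA, OA and UAL, SLC30A1 of 0.47, 0.37 and 0.34, IRF8 of -0.52, -0.23 and -0.24, ABCA1 of -0.50, -0.16 and -0.06, and NR4A3 of -0.68, -0.20 and -0.31. HMOX1 had 0.11, 0.26 and 0.17, and IL6 had -0.26, 0 and -0.09. The metallothionein and zinc export list had blocked camera adjusted p of 0.00889 with UA, 0.081 with OA and 0.0114 with UAL, with adjusted p = 0.663, 0.994 and 0.727 with an estimated correlation. With UA, the alternative activation list had a blocked camera adjusted p of 0.0099 and adjusted p = 0.104 with an estimated correlation, with 11 of 14 genes lower. Macrophage markers (20 of 25 lower) and the 2 endothelial genes each had 0.0374, and adjusted p = 0.125 and 0.451 with an estimated correlation. The mitochondrially encoded genes (10 of 10 higher) had 0.0495 with UA, and adjusted p = 0.997 with an estimated correlation. Their mean differences were 0.15, 0.60 and -0.13 in replicates 1, 2 and 3, and the mitochondrial share of counts differed by 0.33, 1.49 and -0.22 percentage points. With OA, the cholesterol synthesis and uptake list (20 of 24 higher) had 0.0236, and adjusted p = 0.994 with an estimated correlation. Of these lists 0 members passed over all genes, and adjusted over the list alone 2 metallothionein and zinc export genes rose and 1 endothelial gene fell with UA.

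Direct comparisons of the compounds in U937 gave 0 genes past the threshold in edgeR with or without the block for M1 with UA, UA with OA, UA with UAL and OA with UAL. At an unadjusted p under 0.05 these had 104, 97, 163 and 125 genes without the block, DESeq2 called 0 in each, and with the block DESeq2 called 2 for UA with UAL and 0 for the others. These unadjusted counts also lay below a share of 0.05 of the 14329 genes tested. With the block they were 450, 400, 754 and 408, and only that of UA with UAL lay above this share. The 0 calls therefore do not show that the compounds acted alike. Without the filter and with the block, edgeR called 2, 7, 52 and 20. The 95% interval of a blocked log2 difference had a median half-width of 0.28 over all genes and 0.23 over the 9571 genes with a mean of at least 5 CPM. MT1X differed between UA and OA by 0.22 (-0.22 to 0.66), between UA and UAL by 0.13 (-0.31 to 0.57), between OA and UAL by -0.09 (-0.53 to 0.35) and between M1 and UA by 0.30 (-0.14 to 0.73). IL6 differed between UA and OA by -0.26 (-1.01 to 0.49) and between UA and UAL by -0.17 (-0.92 to 0.58). HMOX1 differed between UA and OA by -0.15 (-0.52 to 0.22) and between M1 and UA by 0.08 (-0.29 to 0.45). CYP1A1, a xenobiotic-metabolizing enzyme gene, differed between UA and UAL by -0.54 (-0.84 to -0.24) and between OA and UAL by -0.47 (-0.77 to -0.17). MALAT1 differed between UA and UAL by 0.94 (0.49 to 1.39) and between M1 and UA by -0.78 (-1.23 to -0.33). Between OA and UAL it differed by 0.38 (-0.06 to 0.83). Some other intervals also excluded 0, such as that of CXCL10 between M1 and UA, at -0.85 (-1.62 to -0.07). These intervals are per gene and not adjusted, and the edgeR Benjamini-Hochberg adjusted p of the CYP1A1 differences were 0.788 and 1. That of MALAT1 between UA and UAL was 0.788 in the same test. The difference between the M1 effect and the sum of the UA, OA and UAL effects gave 0 genes in edgeR, with 94 at an unadjusted p under 0.05, and 0 in DESeq2. Without the filter and with the block it gave 4.

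Several lists differed between the compounds in U937 in the blocked camera test with the preset correlation, and none with an estimated one. Cholesterol synthesis and uptake genes were lower with UA than with OA in 21 of 24 cases, with mean log2 differences of -0.12, -0.08 and -0.11 in the 3 pairs, at an adjusted p of 0.000975, and adjusted p = 0.484 with an estimated correlation. They were higher with OA than with UAL in 23 of 24 cases, at 0.15, 0.10 and 0.07, an adjusted p of 0.0013, and adjusted p = 0.684 with an estimated correlation. Between UA and OA, LXR targets were lower and ribosomal proteins higher at 0.014 each, and adjusted p = 0.484 and 0.847 with an estimated correlation. Alternative activation and endothelial genes were also lower with UA than with OA, at 0.0391 each, and adjusted p = 0.393 and 0.484 with an estimated correlation. Between UA and UAL, alternative activation genes were lower at 0.0326, and adjusted p = 0.258 with an estimated correlation. Genes of endoplasmic reticulum stress were lower and mitochondrially encoded genes higher with UA than with UAL, at 0.0268 each, and adjusted p = 0.93 for each with an estimated correlation, with pairs of the latter at 0.41, 0.03 and 0.37. Between OA and UAL, mitochondrially encoded genes were higher at 0.00668 (pairs at 0.48, 0 and 0.28) and glycolysis and hypoxia genes lower at 0.0394, and adjusted p = 0.684 for each with an estimated correlation. Interferon response genes were lower with M1 than with UA at 0.0302, and adjusted p = 0.826 with an estimated correlation, with pairs at -0.27, -0.48 and 0.12. For M1 against the sum of its compounds the list had 0.00447, and adjusted p = 0.991 with an estimated correlation, with pairs at -1.30, -0.60 and 0.55. There its members turned with the fit, with 12 of 35 higher and a median of -0.15 with the block, and 24 higher, a median of 0.17 and a camera adjusted p of 0.945 without it. In these lists 0 members passed over all genes, and adjusted over the list alone 1 did, an endothelial gene lower with UA than with OA.

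OBE and M1 differed in U937 in CYP1A1 and TIPARP, both induced through the aryl hydrocarbon receptor. CYP1A1 (chromosome 15, 74719542 to 74725536) was at 13.7 ± 13.6 CPM with OBE and 27.4 ± 26.8 CPM with M1 (SD, n = 3 each), a blocked log2 difference of -0.99 (SE 0.15), and TIPARP was at -0.82 (SE 0.13). MALAT1 (1.19) and MANF (0.54), a secreted protein of the endoplasmic reticulum, were higher with OBE, and ERCC6 (-0.56) and GAS7 (-0.52) were lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the blocked adjusted p were 0.0128 for CYP1A1 and TIPARP, 0.0444 for MALAT1, 0.0474 for MANF, 0.0218 for ERCC6 and 0.0132 for GAS7. HMOX1 differed by 0.68, with an adjusted p of 0.189 in that test. Of 8 aryl hydrocarbon receptor targets 2 were lower with OBE and 4 adjusted over the list alone, at a blocked camera adjusted p of 8.63e-05, and adjusted p = 0.401 with an estimated correlation. NF-kB targets were lower with OBE in 19 of 19 cases, with 0 past the threshold, also adjusted over the list alone, at a blocked camera adjusted p of 7.87e-05, and adjusted p = 0.591 with an estimated correlation. Ribosomal proteins (24 of 25 higher), oxidative phosphorylation (21 of 23) and heat shock genes (16 of 17) had blocked camera adjusted p of 3.98e-06, 0.000531 and 0.000784, and adjusted p = 0.591 for each with an estimated correlation. Correlations with exon length across genes were -0.25, -0.15 and -0.15 for OBE and 0.11, -0.05 and 0.02 for M1 against activated libraries in replicates 1, 2 and 3. Genes of endoplasmic reticulum stress (18 of 29 higher) and of cholesterol synthesis and uptake (18 of 24) had 0.0222 and 0.0226, and adjusted p = 0.591 for each with an estimated correlation. Interferon response (29 of 35 lower), glycolysis and hypoxia (16 of 24) and immediate early genes (16 of 22) had 0.0291 each, and adjusted p = 0.894, 0.591 and 0.591 with an estimated correlation. In these 8 lists 0 members passed over all genes. Adjusted over the list alone, 9 rose and 1 fell in endoplasmic reticulum stress, 1 rose in heat shock, 2 rose in cholesterol synthesis and 1 rose and 1 fell among immediate early genes. With the block 2 genes were higher and 5 lower. Without it edgeR called 0, with 550 at an unadjusted p under 0.05, and DESeq2 called 2. With the block DESeq2 called 86, and edgeR without the filter 241. The 7 calls became 1 without replicate 1, 0 without replicate 2 and 188 without replicate 3.

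**Figure D4:**
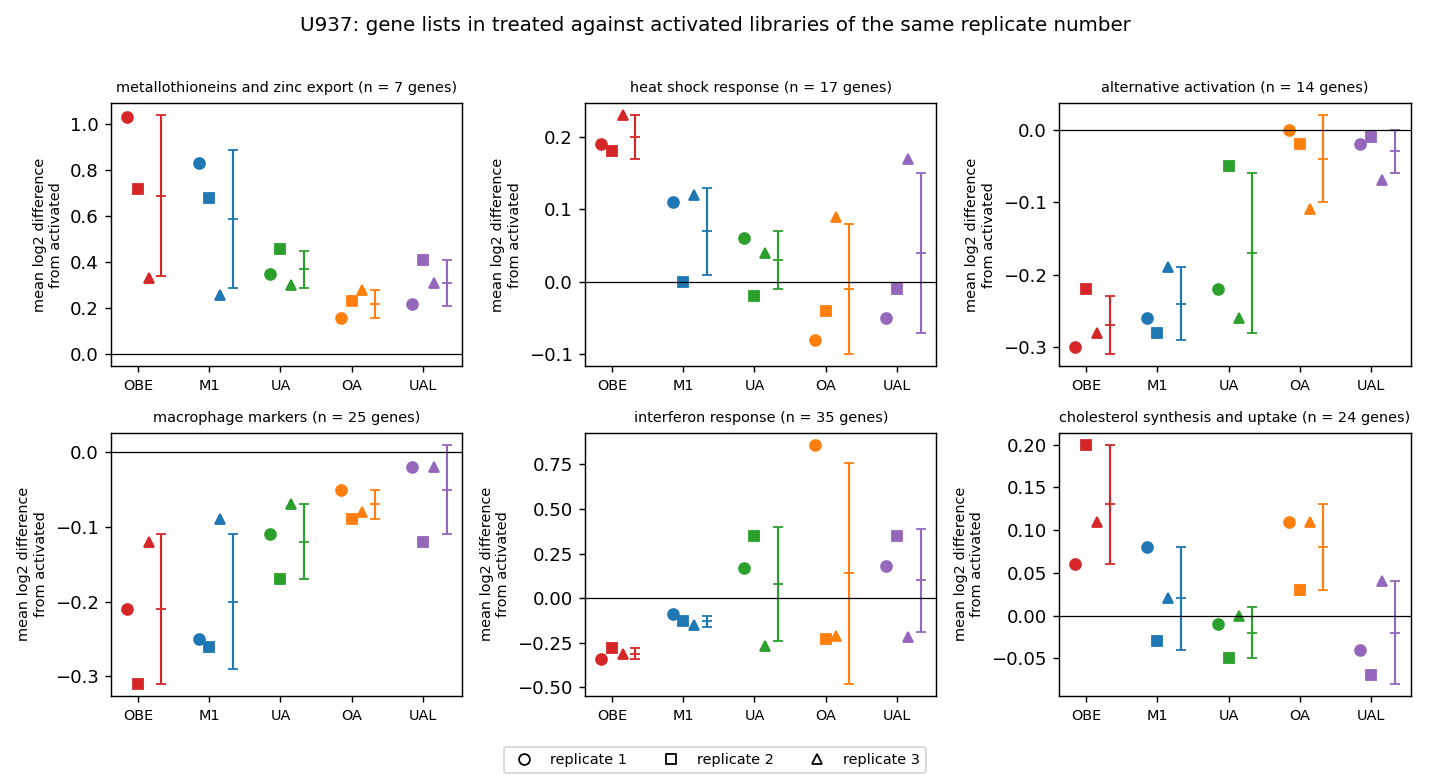
Mean log2 difference of 6 gene lists between treated and activated U937 libraries of the same replicate number, by treatment, with points for the 3 replicates and bars for their mean ± SD. The metallothionein and zinc export list lies above 0 in every treatment and replicate, and the macrophage marker list has means of -0.21 with OBE and -0.20 with M1. Points of the same replicate number share 1 activated library and are not independent. In replicate 3 the metallothionein list had a mean log2 CPM of 5.29 to 5.36 in the treatments, against 5.03 in the activated library.

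In J774, OBE, M1, UA, OA and UAL each gave 0 genes past the threshold against activated libraries in edgeR without the block, and 0 in DESeq2. At an unadjusted p under 0.05 edgeR had 57, 171, 29, 29 and 30 genes. Each was below a share of 0.05 of the 13383 genes tested, the share expected with no effect, as were the direct comparisons below. With the block, OBE, UA, OA and UAL had 454, 116, 119 and 162, also below it. M1 had 1481 and M1 with UA 1680 with the block, both above it, and M1 had 405 without the libraries of replicate 1. Where counts lay below that share the test was conservative, and 0 calls do not show that nothing changed. With the block, ENSMUSG00000040152.9 (chromosome 2, 117942357 to 117957614) fell with OBE by 2.55 on the log2 scale (SE 0.26) and with M1 by 1.77 (SE 0.25), and rose in activation by 3.74 (SE 0.28). Its blocked edgeR Benjamini-Hochberg adjusted p were 0.000405, 0.0281 and 1.14e-06. With OBE it was at 5.7 ± 7.1 against 41.7 ± 61 CPM, and it was lower in 3 of 3 pairs for OBE and for M1. It was the 1 gene called by edgeR with the block in each of these treatments, and UA, OA and UAL had 0, against 2, 2, 0, 0 and 1 by DESeq2 with the block. The call was lost without replicate 2 for OBE, and without replicate 2, without replicate 3 or with exon length correction for M1. M1 replicate 1 stood apart on the second principal component, at -83.7, against -32.4 to 2.5 for the other activated and treated libraries of its number, and without replicate 1 the count for M1 was 1. The direct comparisons gave 0 genes in edgeR, with 44 (OBE and M1), 192 (M1 and UA), 22 (UA and OA), 19 (UA and UAL) and 11 (OA and UAL) at an unadjusted p under 0.05, and 0 in DESeq2, and the test of M1 against the sum of its compounds gave 0, with 48. Without the filter and with the block, edgeR called 22 for OBE, 95 for M1, 0 for UA, 20 for OA, 21 for UAL and 208 for M1 with UA.

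Overlap between effects in U937 was examined in the blocked fit. OBE and M1 shared 10 fallen genes and 0 risen ones, against 0.261 fallen for independent lists and a mean of 0.02, at most 1, shared in 100 simulations with no effect. Data simulated with no effect hold few calls, so their shared count does not measure how far shared libraries raise the overlap of real effects. The covariance of the OBE and M1 log2 fold changes across 14329 genes was 0.0521, against 0.0294 simulated. It was 0.048 against 0.0295 for OBE with UA and 0.0431 against 0.0294 for M1 with UA, and 0.0302 against 0.0295 for OBE with OA and 0.0291 against 0.0296 for OBE with UAL. Of genes called in both activation and OBE, 59 rose in activation and fell with OBE (24.8 for independent lists), 16 fell and then rose (10.5), 6 rose in both (10.1) and 38 fell in both (25.7), against a simulated mean of 0.03 and at most 2 for all 4 together. The covariance of activation with OBE was -0.0382, against -0.0295 simulated. Part of the excess of OBE with M1, and of genes called in opposite directions in activation and OBE, may come from the shared activated libraries, which were too few to split. For genes called in the same direction in activation and OBE, sharing them acts the other way. Genes are not independent replicates. In J774 the covariance of OBE with M1 was 0.0697 against 0.0554 simulated, and that of OBE with UA 0.0336 against 0.0554. The first lay above the highest simulated value (0.0624) and the second below the lowest (0.0481). The simulation, which drew genes independently, may thus misstate the covariance that shared libraries give. Neither an excess nor a shortfall against it, in either line, measures how far effects are shared.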

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

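The tests fixed beforehand were DESeq2, RLE, no filter, only the libraries of a comparison, the replicate block, an estimated correlation and leaving out 1 library, and all others, which combine a setting with the block, were chosen only after the results were seen. Counts of changed genes without a block stayed within 1.5 times their value in 252 of the recomputed values, left that range in 12 and rose from 0 in 18, and counts with the block stayed in 21 and left it in 35. For single genes, 1483 values kept direction and side of the threshold, 536 lost the threshold, 24 gained it and 33 turned direction. The cause of the differences was not tested. The median half-width of a 95% interval was 0.28 over all U937 genes and 0.23 over those with at least 5 CPM, and how far depth limits it was not tested apart from other spread.

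With the replicate block, calls in activation went from 0 to 1366 in J774 and from 144 to 2509 in U937. Calls in OBE went from 0 to 1 in J774 and from 0 to 406 in U937, those in M1 from 0 to 1 and from 0 to 14, and those in U937 OBE against M1 from 0 to 7. The block changed the count of no other comparison. DESeq2 without the block called 8 genes in J774 activation and, in U937, 452 in activation, 31 in OBE and 2 in OBE against M1. Without the filter there were 185 in J774 activation and 1 in J774 M1 against UA. In U937, leaving out the filter gave 794 in activation, 64 in OBE, 13 in M1, 1 in UA, 9 in OBE against M1, 2 in UA against UAL and 1 in OA against UAL. U937 activation had 0 calls when only its own libraries were fitted. Leaving out 1 library gave 10 (control replicate 1), 15 (activated replicate 1), 22 (activated replicate 2), 23 (control replicate 2) and 255 (activated replicate 3) calls in U937 activation, and 7 in U937 OBE without OBE replicate 3. The cause was not tested.

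For the blocked counts, DESeq2 called 2 genes in J774 OBE, 2 in J774 M1, 652 in U937 OBE, 102 in U937 M1 and 86 in U937 OBE against M1. Without the filter these were 22, 95, 849, 274 and 241. Comparisons with 0 blocked calls had calls without the filter and with the block: in J774 20 for OA, 21 for UAL, 5 for OBE against M1, 208 for M1 against UA, 7 for UA against OA, 4 for UA against UAL, 1 for OA against UAL and 16 for M1 against the sum of its compounds. In U937 there were 30 for UA, 1 for OA, 9 for UAL, 2 for M1 against UA, 7 for UA against OA, 52 for UA against UAL, 20 for OA against UAL and 4 for M1 against the sum. DESeq2 with the block called 1 gene in J774 UAL and 2 in U937 UA against UAL, where edgeR called 0, while edgeR called 3 in U937 UA without replicate 3 and 1 in J774 OA against UAL without replicate 1. Exon length correction gave 0 in J774 M1 and 11 in U937 OBE against M1. Without all libraries of replicate 1, the counts were 539 in J774 activation, 704 in U937 activation, 0 in U937 OBE, 0 in U937 M1 and 1 in U937 OBE against M1. Without replicate 2 they were 106 in J774 activation, 0 in J774 OBE, 0 in J774 M1, 266 in U937 activation, and 0 in U937 OBE, M1 and OBE against M1. Without replicate 3 they were 1305 in J774 activation, 3706 in U937 activation, 0 in J774 M1, 1817 in U937 OBE, 499 in U937 M1 and 188 in U937 OBE against M1. The cause was not tested. Of 37 gene list calls over the U937 comparisons, 0 were left with an estimated correlation, 64 lists were called with the replicate block, and 4 with both.

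Direction turned when libraries were left out in key genes that had not passed the same fit with all libraries, and the cause was not tested. One of them, CXCL10 in activation, passed with the block (1.30), and its turned value is from the fit without it. With the block, leaving out the libraries of 1 replicate number gave -0.17 to 0.01 for CCL2 in OBE and -0.04 to 0.15 for PTGS2 in M1, with the turned values without replicate 2 and without replicate 1. Without the block, leaving out 1 library gave -0.29 (without activated replicate 3) to 2.45 for CXCL10 in activation. In OBE it gave -1.33 to 0.04 for PTGS2, -0.69 to 0.42 for IL10, -0.41 to 0.22 for IL1B, -3.60 to 1.38 for CXCL10, -0.96 to 0.66 for TNF, -1.43 to 0.27 for IL6 and -0.24 to 0.13 for CCL2. In M1 it gave -0.59 to 0.77 for PTGS2, -0.61 to 0.54 for IL10, -0.20 to 0.46 for IL1B, -2.47 to 1.25 for CXCL10, -0.48 to 1.04 for TNF, -1.40 to 0.24 for IL6 and -0.07 to 0.52 for HMOX1. The ends lay at activated replicate 1 for IL10, TNF and IL6 in both treatments (upper end), and at activated replicate 3 for CXCL10 (upper end).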

Other observations

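The ratio of depths, the counts over other splits of the libraries, the comparison of list levels and of list differences by replicate number, the other filters on strong risers and the exact intervals were chosen only after the results were seen. Interferon response genes lay higher in replicate 3 of U937 than in the other replicates. The mean log2 CPM of the 35 genes was highest in replicate 3 in 7 of 7 groups, control included, at 4.8 to 5.28, against 1.94 to 3.6 in replicates 1 and 2. Alternative activation, heat shock, macrophage marker and metallothionein lists were highest in replicate 3 in 0 of 7 groups, and the inflammatory cytokine and chemokine list in 1 of 7.

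In U937, the differences between OBE and activated libraries in replicate 3 did not follow those of replicates 1 and 2, with correlations across genes of 0.06 and 0.06, against 0.72 between replicates 1 and 2 (genes are not independent replicates). After removal of a trend on exon length, the higher of these correlations was 0.05. The OBE differences had Spearman correlations with exon length of -0.25, -0.15 and -0.15 in replicates 1, 2 and 3. A trend of the same sign in each replicate adds agreement, and its removal could hardly raise the correlations. This test therefore cannot decide whether such a trend played a part. An exchange of the OBE and activated libraries of replicate 3 would turn the signs there, and it is argued against by the fixed gene lists: of 21 with the same sign in replicates 1 and 2, 18 had it in replicate 3 (85.7%, exact 95% interval 63.7 to 97, with lists not independent), such as metallothioneins at 1.03, 0.72 and 0.33 and alternative activation at -0.30, -0.22 and -0.28. Of 1816 genes called without replicate 3, 57.8% had the same sign in it (55.5 to 60.1), above the 30% set beforehand as the most for an exchange but short of the 60% set as the least without one, with 294 of 716 risers higher (median -0.06) and 756 of 1100 fallers lower (median -0.11). The differences of replicate 3 were not smaller over all genes (SD of log2 differences 0.28, against 0.33 and 0.27), and a smaller response to OBE beside another source of variation was not tested.

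Activation changed genes less in replicate 3 than in replicates 1 and 2 in both lines, with an SD of log2 differences of 0.26 against 0.55 and 0.43 in U937 and 0.34 against 0.88 and 0.53 in J774. Lower depth is argued against by the ratio of mean totals, 0.99 at the lowest. In J774, RNA of activated cells in the control library of replicate 3 was tested with bounds set beforehand. The filter first used passed the 25% bound against mixing, with an interval that spans it. A rule that a second filter must pass as well was chosen after the results were seen. By that rule the question is left open. There, of 184 strong risers the 31 with at least 20 CPM in activated replicate 3 had a control to activated ratio below 0.5 of the share of RNA that the median riser would need (24.9%) in 25.8% of cases (exact 95% interval 11.9 to 44.6). The 77 with at least 20 CPM in activated replicates 1 and 2 had it in 22.1% (13.4 to 33), with 20.7 to 25.8% over the 8 filters tried. These lie above the 5% set beforehand as the limit for mixing and on both sides of the 25% set as the least without it. The 184 risers were lower in control replicate 3 than in controls 1 and 2 (median log2 difference -0.4), where mixing would raise them, and lower in activated replicate 3 (-1.72). They were selected by their rise in replicates 1 and 2, which by itself favours lower activated and higher control values in replicate 3. For these genes the control values go against that selection and argue against mixing as the main source, though they rest on 1 control library. In U937, where the median riser would need 40.9%, 0% of 37 risers (0 to 9.5) lay below 0.5 of it, so such mixing may have occurred. The risers were higher in control replicate 3 than in controls 1 and 2 (median log2 difference 0.46) and lower in activated replicate 3 (-0.69). Both may come in part from the same selection, so neither weighs for or against mixing. A weaker response would also give the 0% and stays open.

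In J774, the differences between M1 and activated libraries in replicate 1 ran against those of replicate 3, with a correlation across genes of -0.46, and 1725 genes differed over 2-fold in replicate 1 against 22 and 7 in replicates 2 and 3. A trend on exon length is argued against as the whole cause, since the correlation was -0.29 after its removal. It may be part of the cause, as the M1 differences had Spearman correlations with exon length of -0.49, -0.57 and 0.5 in replicates 1, 2 and 3. After its removal, 1065 genes were over 2-fold in replicate 1, and the correlation of replicates 2 and 3 went from -0.38 to -0.14. Without the top 50 genes, 1715 of 8892 genes were still over 2-fold in replicate 1. TMM normalization already offsets genes that take many counts, with or without the top 50. This test therefore could hardly come out otherwise, and it cannot decide whether a few genes taking most of the counts played a part. A second control library in place of M1 replicate 1 is argued against by a slope of 0.16, where 0.8 or more was set beforehand. No biological explanation was tested.

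Splits of 3 against 3 libraries number 10 and those that part each of 3 pairs number 4, too few for a share under 0.05. Without a block, U937 activation had 144 calls in the real split and at most 0 in the others. The other unblocked comparisons with 3 libraries in each group had 0 calls in the real split and at most 0 in the others (10 of 10 splits as large). With the block, the real split and the highest other had 1366 and 7 calls in J774 activation, 1 and 0 in J774 OBE, 1 and 0 in J774 M1, 2509 and 17 in U937 activation, 14 and 0 in U937 M1, and 7 and 0 in U937 OBE against M1. In U937 OBE they had 406 and 228, and the split with 228 calls was the one that exchanged the libraries of replicate 3, while exchanging those of replicate 1 or 2 gave 0. That split follows the difference of replicate 3 described above.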
